A study of Mus musculus with 6 samples.

How the data were processed

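RNA from bladder cells of male FVB/N mice at postnatal day 2 was measured on 6 Affymetrix MOE430 arrays, 1 per sample. Per the labels' protocols, tissue was dissected, digested with enzymes and sorted by fluorescence. RNA was extracted with RNeasy columns, amplified in 2 rounds with a TargetAmp kit and labelled with biotin, and samples were not pooled. Amplification in 2 rounds starts from the 3' end of transcripts, so that probe sets far from that end can lose signal. The deposited table holds a linear signal intensity per probe set. GCOS, the Affymetrix operating software, is the tool named per the submitters' processing notes, and its algorithm, version and scaling target are not given in the sources used here. The mean after trimming 2% at each end was 1500.01 on every array, so the deposited intensities had been scaled to a common level. Such scaling sets the trimmed mean of each array equal, and a true difference in total RNA per cell cannot be seen. No detection calls were used here.

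Samples were grouped by the reporter state that their titles give. Probe sets were named from the platform annotation. Of 45037 probe sets other than the 64 controls, 34945 had 1 gene symbol, 932 had several and 9160 had none listed. Entrez identifiers matched 34741 of the first kind to a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. The array table names no genome build, so no positions are given. Probe sets with several symbols were not named.

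Values were converted to log2(signal + 25.042), the offset being the 20th percentile of all values. Arrays were not rescaled, since their medians differed 1.36-fold, under the limit of 1.5 set beforehand. Each gene was represented by the probe set with the highest mean, and genes were kept when that mean was above the 40th percentile of probe set means (6.82 on the log2 scale), which left 13464 of 18193 genes. Choosing the brightest probe set favours signals near the top of the range, where a difference can be compressed. For named genes and list members that passed over all probe sets, no other tested probe set of the gene passed in the opposite direction. Passing in the same direction was not general either. It held for the other tested probe sets of Bmp5, Wnt4 and Cxcl14. It held for none of those of Ptch1 (2 others), Smad3 (2), Rrm2 (2) and Mef2c (4), among further genes.

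Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are those of the moderated fit. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 22 lists with at least 5 tested members, again with a correlation estimated from the data, and with fry. In all 23 lists were fixed, and some share members. Single values were compared with exact two-sided permutation tests. Before the data were examined, the samples, the limma and list tests of the report, its gene lists, the alternatives other than the Actb covariate and the rule for naming genes were fixed, while several tests of explanations were chosen later. The rule took the 14 genes of largest positive and the 14 of largest negative change among those past the threshold with groups that did not overlap, leaving out clone and gene-model names. It also took Actg2, Acta2 and, of each list, the 3 members of smallest p and all members past the threshold where they were 5 or fewer. Where a list had more than 5 past the threshold, members named beyond the first 3 were chosen after their values were seen.

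The procedure was tested on simulated data for 13464 genes. It recovered 5% of simulated log2 changes of 1 and 43% of log2 changes of 2, and 3 of its 51 calls were false. In this simulation a change of less than 4-fold was therefore often missed. The real comparison called 857 genes, and the adjusted threshold is less strict where more genes pass. Recovery in the real data can therefore differ from these rates. Without a shift 0 of 22 simulated lists were called, and a shifted list was called. The simulated noise was independent between genes, while members of real lists can vary together (estimated correlation up to 0.47 here). The false call rate of such lists was therefore not tested. Alternatives covered quantile normalization, median centring, other offsets and filters, other choices of probe sets, no variance trend, array weights, the replicate number as a block, and leaving out each array. The ratio of 3' to 5' Actb control signal as a covariate was chosen after seeing the data. No 2 arrays held identical values for more than 13 probe sets. The labels give no scan date or batch.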

Results

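Bladder cells of male FVB/N mice at postnatal day 2 were compared between 2 sorted populations. The mice carried a pair of transgenes, EGFP under the promoter of smooth muscle gamma actin (endogenous gene Actg2) and EYFP under the promoter of smooth muscle alpha actin (endogenous gene Acta2). Cells with EGFP and without EYFP (single-positive, 3 arrays) were set against cells with both reporters (double-positive, 3 arrays), and the labels place both populations in the detrusor, the muscle layer of the bladder wall. Each array gave 1 signal intensity per probe set, in arbitrary units. Median signal was 173.6 ± 23.2 (SD, n = 3) in the single-positive and 166.7 ± 28.8 (SD, n = 3) in the double-positive arrays. Pearson's r of log2 signals across probe sets, which are not independent replicates, was 0.949 to 0.963 between single-positive arrays, 0.930 to 0.941 between double-positive arrays and 0.890 to 0.923 between the groups. The number of arrays limits the precision. Nothing in the labels says that the 3 arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Groups are named as labelled, and fold changes are double-positive over single-positive on the log2(signal + 25.042) scale, which understates the change of dim genes.

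The comparison asks how the cells with both reporters differ from those with the gamma actin reporter alone, and the actin genes behind the reporters were read first. Actg2 signal was 5.81-fold lower in the double-positive arrays, 10595 ± 3281 against 60131 ± 8405 (SD, n = 3 each). Its log2 fold change was -2.54 (SE 0.22, limma adjusted p = 0.000246), and all 3 double-positive values lay below all 3 single-positive values. The single-positive values ranked 12, 41 and 36 on their arrays, near the top of the range. Differences can be compressed there, which was not tested, so the fold is approximate. Acta2 signal on the probe set used for the gene, the brightest of 3, was 59801 ± 11165 in double-positive and 62346 ± 9277 in single-positive arrays (SD, n = 3 each). That difference, a log2 fold change of -0.07, was smaller than the spread between arrays (exact two-sided permutation p = 0.9, where 0.1 is the smallest p that 3 against 3 allows). This probe set ranked between 11 and 117 among the 45037 probe sets of an array, near the top of the range, and its suffix marks it as shared between transcripts.

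The other Acta2 probe sets gave another picture. On the next brightest the signal was 371 ± 92.5 in double-positive and 7770 ± 1667 in single-positive arrays (SD, n = 3 each), 19.8-fold lower, with an adjusted p of 0.000954 over all probe sets in limma. On the dimmest the log2 fold change was -3.07 (SE 0.81, limma adjusted p = 0.141), which did not pass. No Acta2 probe set was higher in the double-positive arrays past the threshold, although the sort selected those cells for EYFP driven by the Acta2 promoter.

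Of 13464 genes tested with limma, 857 passed an adjusted p of 0.05, with 267 higher and 590 lower in the double-positive arrays. A change of at least 4-fold was seen for 94 of the higher and 361 of the lower genes. The groups did not overlap for 3019 of the tested genes (22.4%, where chance gives 10%), among them all 857 that passed. The total was 497 without single-positive array 2 and 474 without single-positive array 3. The genes lower in double-positive arrays numbered 392 without single-positive array 1, and the higher genes numbered 160 without double-positive array 1. With array weights the total was 1345.

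Among the 14 genes named for the largest rise in the double-positive arrays, Cxcl14, a chemokine, rose from 233 ± 86.1 to 10420.4 ± 4979.6 (SD, n = 3), a log2 fold change of 5.26 (SE 0.44, limma adjusted p = 0.000235). Bmp5, a bone morphogenetic protein, rose from 3124 ± 961 to 40911 ± 2671 (log2 fold change 3.75, SE 0.24, limma adjusted p = 9.88e-05). Wnt4, a Wnt ligand, had a log2 fold change of 3.88 (SE 0.37). Dkk2, a secreted Wnt regulator, had one of 3.66 (SE 0.51), and Lef1, a transcription factor of the Wnt pathway, one of 3.71 (SE 0.63). The peptide hormone genes Apela, Sct (secretin) and Cck (cholecystokinin) had log2 fold changes of 4.03, 3.93 and 3.60. Ntng1, a netrin-related membrane protein, had 5.68 (SE 0.80), and the remaining genes of largest rise were Ly75 (4.92), Kcnc2 (4.61), Tex14 (3.90), Aox3 (3.87) and the urea transporter Slc14a1 (3.52). Ly75, Kcnc2, Sct, Ntng1 and Tex14 had mean log2 values of 5.41, 5.16, 6.15, 6.52 and 6.80 in the single-positive arrays, below the level of the filter on dim genes (6.82), so their folds rest on the offset. Without single-positive array 1 the log2 fold changes of Ntng1, Lef1 and Dkk2 were 4.94, 2.88 and 2.99, and without single-positive array 3 that of Ntng1 was 6.82.

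Among the 14 genes named for the largest fall, Pcp4, a calmodulin-binding peptide, fell from 4502 ± 436 to 46.5 ± 64.7 (SD, n = 3), a log2 fold change of -6.35 (SE 0.55, limma adjusted p = 0.000235). Acta1, skeletal alpha actin, fell from 38354 ± 5949.8 to 1493 ± 827 (log2 fold change -4.85, SE 0.42), and Fhod3, a formin of muscle sarcomeres, had a log2 fold change of -5.20 (SE 0.67). Shh, a Hedgehog ligand, had one of -4.68 (SE 0.57). Mbp, myelin basic protein, had one of -4.80 (SE 0.44), but with a smaller offset another of its probe sets stood for the gene and gave -0.32 (adjusted p = 0.765). Ripk4 (-5.82), Rims1 (-5.39), Nipal4 (-5.36), Tmem71 (-5.33), Nrros (-5.33), Sntg2 (-5.31), Mal (-5.07) and Popdc3 (-4.74) completed the group with Sh3bgr (-5.06, SE 1.17, limma adjusted p = 0.0288). Sh3bgr missed the threshold without any 1 of the 3 single-positive arrays, with adjusted p between 0.0704 and 0.104. Pcp4, Ripk4, Rims1, Nipal4, Tmem71, Nrros, Mal and Shh had mean log2 values of 5.79, 5.20, 6.64, 4.97, 4.98, 6.11, 6.74 and 6.66 in the double-positive arrays, also below the level of the filter, so their folds rest on the offset too. Several values moved when 1 array was left out. Without double-positive array 1, Fhod3, Rims1, Sh3bgr and Nrros had -4.23, -4.65, -3.24 and -6.01. Without double-positive array 2, Rims1, Sh3bgr and Shh had -6.56, -6.14 and -5.29. Without double-positive array 3, Pcp4, Fhod3, Mal and Sh3bgr had -7.05, -5.85, -4.16 and -5.81, and without single-positive array 1 Tmem71 had -4.68.

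Of 31 contractile genes of smooth muscle tested, 21 fell in the double-positive arrays, none rose and 10 did not pass, and 26 passed when adjusted over the list alone. Synm, an intermediate filament protein, fell 23.3-fold from 31512 to 1481. Cnn1 (calponin), Des (desmin), Myh11 (smooth muscle myosin heavy chain) and Tagln (transgelin) had log2 fold changes of -4.25, -3.26, -3.23 and -2.86. Mylk, myosin light chain kinase, and Actn1 fell less, by 0.79 and 0.66 on the log2 scale. The list's median was -1.82 with a camera adjusted p of 4.63e-26, and its adjusted p was 0.0650 with an estimated correlation.

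**Figure D1:**
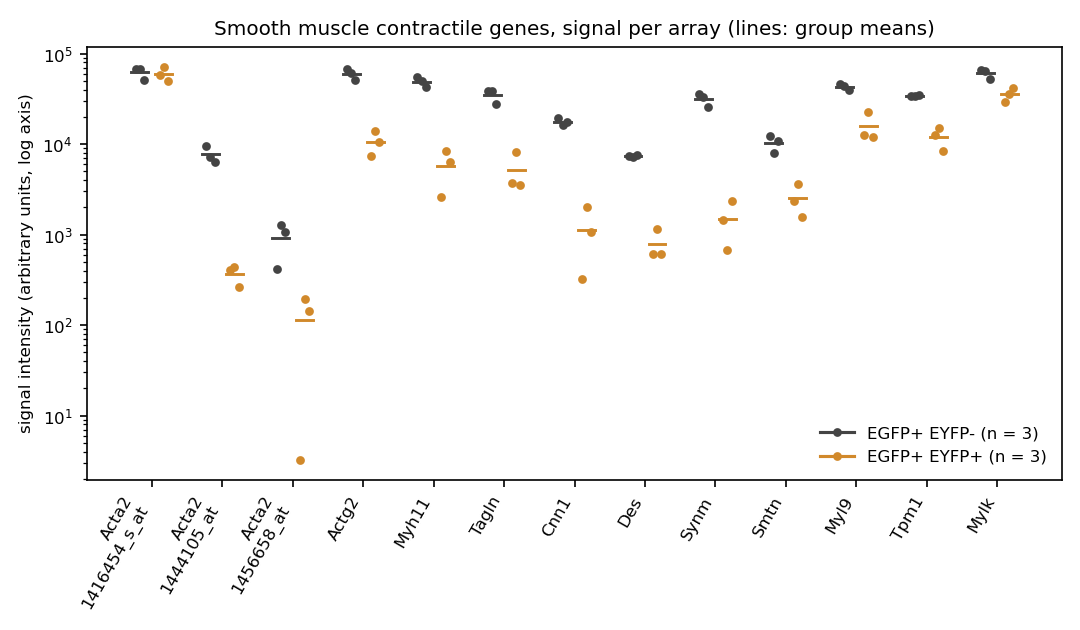
Signal intensity of 3 Acta2 probe sets and 10 other smooth muscle genes on each array (arbitrary units, log axis), with a point per array and a line at each group mean (n = 3). Actg2 lies near 60131 in the single-positive and 10595 in the double-positive group, while the brightest Acta2 probe set lies near 62346 and 59801.

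Of 22 genes of detrusor excitability tested, 5 fell, none rose and 17 did not pass, with 9 passing when adjusted over the list alone. The other 10 of the 32 genes in the list were not tested, Chrm2, Chrm3 and Adrb3 among them. P2rx1, the ATP receptor of bladder muscle, fell from 4544 ± 1962 to 263 ± 105 (SD, n = 3), a log2 fold change of -3.98 (SE 0.42, limma adjusted p = 0.000521). Pln (phospholamban), Kcnmb1 (a subunit of the BK potassium channel), Ptger3 and Cacna1c had log2 fold changes of -3.33, -2.0, -1.41 and -1.33, the first from a mean log2 value of 6.73 in the double-positive arrays, below the level of the filter. Camera gave an adjusted p of 2.2e-06, and the adjusted p was 0.0733 with an estimated correlation. The 5 became 2 without single-positive array 2 or 3, 3 without single-positive array 1 or double-positive array 1 or 2, and 8 without double-positive array 3.

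Transcription factors of smooth muscle development went both ways. Foxf2, Foxf1 and Tcf21 rose, with log2 fold changes of 3.02 (SE 0.40), 1.4 (SE 0.24) and 1.12 (SE 0.18), and Mef2c fell (-1.81, SE 0.44, limma adjusted p = 0.0351). The remaining 19 of 23 did not pass, and 4 passed when adjusted over the list alone. The list was not called by camera (adjusted p = 0.810, and adjusted p = 0.841 with an estimated correlation). No member fell when any 1 of the 3 single-positive arrays, or double-positive array 1 or 2, was left out, and 3 fell without double-positive array 3. Foxf2 did not pass when averaged over its probe sets (1.14, adjusted p = 0.0730).

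Genes of the Hedgehog, BMP and Wnt pathways held most of the list members that rose. In the Hedgehog list of 13, 6 rose (Ptch1, Hhip, Gli1, Foxf2, Foxf1 and Bmp4), 2 fell (Gas1 and Cdon) and 5 did not pass. Ptch1, the Hedgehog receptor and a transcriptional target of the pathway, rose from 16126 ± 3899 to 48024 ± 1230.0 (SD, n = 3, log2 fold change 1.60, SE 0.18, limma adjusted p = 0.000743). The 2 other tested probe sets of Ptch1 were higher as well but did not pass. Hhip and Gli1, which are targets as well, had log2 fold changes of 3.48 (SE 0.44) and 2.04 (SE 0.33). The coreceptors Gas1 and Cdon had log2 fold changes of -1.18 and -1.86. When adjusted over the list alone, 8 passed. The list's median was 0.49 with a camera adjusted p of 0.0018, and the adjusted p was 0.0882 with an estimated correlation. The ligand Shh, a member of the urothelium list, fell in the same arrays. The 6 rises numbered 6 without any 1 array, and the 2 falls numbered 0 without single-positive array 1 or 2, and 1 without single-positive array 3 or double-positive array 1.

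In the TGF-beta and BMP list, 6 of 24 rose, none fell and 18 did not pass. Without double-positive array 3, 8 rose and 3 fell, and with array weights 8 rose and 2 fell. Beside Bmp5, the ligands Bmp7, Bmp2 and Bmp4 had log2 fold changes of 2.79 (SE 0.33), 2.31 (SE 0.26) and 1.65 (SE 0.29). Smad3, a signal transducer of TGF-beta, and Id3, a target of BMP signals, had 0.96 and 0.85. When adjusted over the list alone, 10 passed, 9 higher and 1 lower. The camera call was upward (adjusted p = 0.00762) and the mean was 0.47, while the median was slightly below 0 at -0.0072. The adjusted p was 0.111 with an estimated correlation. Bmp4 also stands in the Hedgehog list.

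In the Wnt list, 7 of 23 rose, 1 fell and 15 did not pass, with 11 passing when adjusted over the list alone. Notum and Axin2, which restrain Wnt signals and are induced by them, had log2 fold changes of 2.50 (SE 0.44) and 1.23 (SE 0.31). The ligand Wnt2 had 1.28 and the receptor Fzd1 had 0.71. Nkd2, an inhibitor of the pathway, had -1.70 (SE 0.32, limma adjusted p = 0.0115). The median of the Wnt list was 0.44 with a camera adjusted p of 0.0018, and the adjusted p was 0.183 with an estimated correlation. The 7 rises became 4 when single-positive array 2 or 3, or double-positive array 1 or 2, was left out, and the fall was lost without single-positive array 1.

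**Figure D2:**
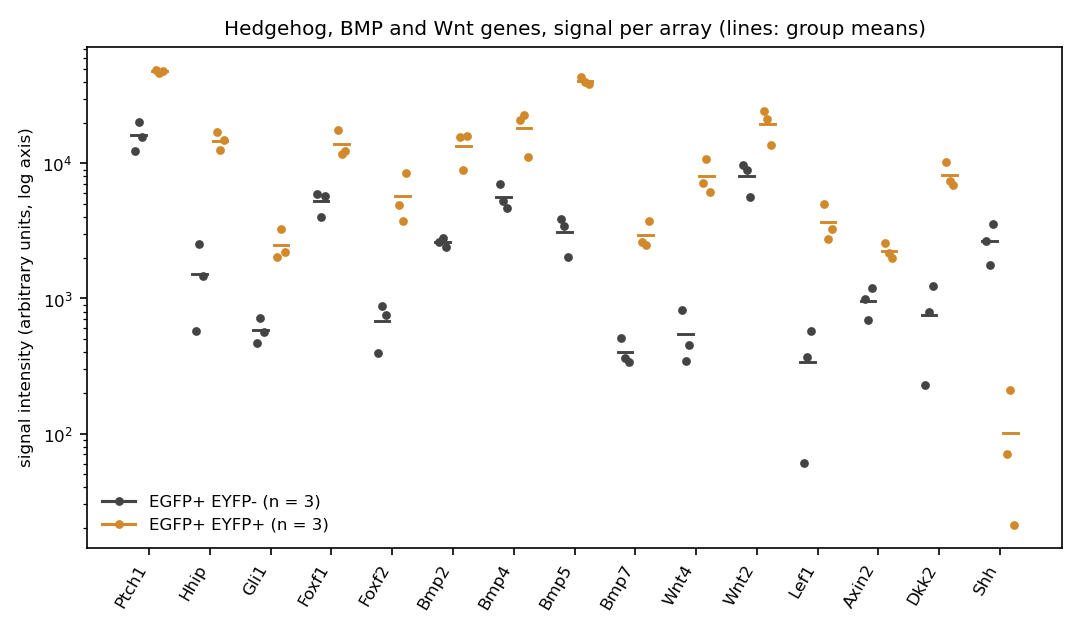
Signal intensity of 15 Hedgehog, BMP and Wnt genes on each array (arbitrary units, log axis), with a point per array and a line at each group mean (n = 3). Shh is the gene plotted with a lower signal in the double-positive group, at a mean of 101 against 2678. The other genes plotted were picked from the list members that rose. Gas1, Cdon and Nkd2, which fell past the threshold, and members that did not pass are not plotted. The plot therefore does not show how the lists moved as a whole.

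Cell cycle genes leaned upward in the double-positive arrays by small amounts. Top2a, Rrm2, Cks2 and Ccnb2, which serve DNA replication and mitosis, had log2 fold changes of 0.84, 0.74, 0.72 and 1.08. These 4 rose out of 31, none fell, 27 did not pass, and 10 passed when adjusted over the list alone. Averaged over its probe sets Top2a had 0.28 and did not pass (adjusted p = 0.793). The camera adjusted p was 4.07e-11, and the adjusted p was 0.0650 with an estimated correlation. No member passed without single-positive array 2 or without double-positive array 1, while 1 passed without single-positive array 3 and 2 without single-positive array 1. With no variance trend 0 passed, and with array weights 9.

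Markers of other cell types were read as well, although both populations were sorted as EGFP positive. Of 21 leukocyte markers, 19 fell and 2 did not pass, and 19 passed when adjusted over the list alone. Mrc1, the macrophage mannose receptor, fell from 26083 ± 3008 to 3482 ± 1181 (SD, n = 3; log2 fold change -2.96, SE 0.27, limma adjusted p = 0.00028), and Csf1r and Cd14 had -2.68 and -2.66. Laptm5 had -3.07 on a probe set shared between transcripts and -0.52 (adjusted p = 0.566) on an unshared one. The leukocyte list had a camera adjusted p of 1.69e-25, and an adjusted p of 0.0601 with an estimated correlation.

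In the nerve and Schwann cell list, 7 of 14 fell and 7 did not pass, with 10 passing when adjusted over the list alone. A lower value was seen for 13 of the 14 and a higher one for 1, Sox10. Its mean log2 value was 8.33 in double-positive and 8.08 in single-positive arrays, and that of S100b was 9.37 and 9.77. Erbb3, a neuregulin receptor of Schwann cells, and Snap25, a synaptic protein, had log2 fold changes of -4.33 (SE 0.41) and -4.18 (SE 0.42), the second from a mean double-positive signal of 14.7, below the level of the filter, and L1cam had -2.16, or -0.86 averaged over its probe sets (adjusted p = 0.301). Camera gave an adjusted p of 1.1e-09, and the adjusted p was 0.0601 with an estimated correlation. The 7 became 4 without single-positive array 3.

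In the urothelium list, 12 of 22 fell and 10 did not pass, with 12 passing when adjusted over the list alone. Beside Shh, Perp (a desmosomal protein) had a log2 fold change of -3.60 (SE 0.26), Krt15 had -3.36 from a mean double-positive signal of 14.4, also below that level, and the uroplakins Upk1b and Upk3a had -3.17 and -2.75. The camera adjusted p was 3.65e-12, and the adjusted p was 0.144 with an estimated correlation. The 12 became 7 without single-positive array 2 or 3. In the mesothelium list, 4 of 6 fell, 2 did not pass, and 4 passed when adjusted over the list alone. Of these Krt8, Krt18 and Krt19 are also urothelium members, and Cpe (-2.60) is not. The 2 that did not pass, Upk3b and Wt1, were not lower. Their mean log2 values were 9.21 and 7.75 in double-positive and 9.09 and 7.52 in single-positive arrays. Camera gave an adjusted p of 0.00163, and the adjusted p was 0.183 with an estimated correlation. The 4 became 1 without single-positive array 2 or 3, and 2 without single-positive array 1.

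In the endothelium list, 9 of 19 fell and 10 did not pass, with 15 passing when adjusted over the list alone. Lyve1, a receptor of lymphatic endothelium and of some macrophages, fell from 20884 ± 3225 to 2425 ± 1427 (SD, n = 3), Cdh5 (vascular endothelial cadherin) had a log2 fold change of -2.41 (SE 0.33), and Sox17 had -3.99 on a shared probe set and -0.70 (adjusted p = 0.471) on an unshared one. The camera adjusted p was 5.08e-11, and the adjusted p was 0.144 with an estimated correlation. The 9 became 4 without single-positive array 2 or 3 and 5 without double-positive array 1.

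In the pericyte and vascular smooth muscle list, Avpr1a (a vasopressin receptor) rose with a log2 fold change of 3.08 (SE 0.40), Mcam, Itga1, Rgs4, Gucy1a1 and Rgs5 fell, and 13 of 19 did not pass. When adjusted over the list alone, 10 passed. The camera adjusted p was 0.0441 and went above the threshold in several settings, reaching 0.174 without double-positive array 1. The adjusted p was 0.406 with an estimated correlation. The 5 falls became 3 without single-positive array 2 or 3 or double-positive array 1 or 2, and 2 members rose without double-positive array 3. Of 7 markers of interstitial cells of Cajal, the pacemaker cells of smooth muscle organs, Gucy1a1, Prkcq and Kit fell and 4 did not pass. When adjusted over the list alone, 3 lower members and 1 higher member passed. A higher value was seen for 3 members, among them Ano1 (mean log2 13.30 in double-positive and 12.10 in single-positive arrays). Over all genes 1 member rose without single-positive array 2 and with the replicate block. Kit missed the threshold when any 1 array other than double-positive array 3 was left out, with adjusted p up to 0.110, and Prkcq had a mean double-positive signal of 23.7, below the level of the filter. Their list was not called (camera adjusted p = 0.108, and adjusted p = 0.478 with an estimated correlation) but was called without single-positive array 1 (adjusted p = 0.0298) and without double-positive array 3 (0.0324).

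Striated muscle markers fell for 5 of 16, with 11 not passing and 7 passing when adjusted over the list alone. Beside Acta1, Ckm (muscle creatine kinase), Casq1, Tnnt1 and Tnnt3 had log2 fold changes of -3.79, -3.24, -3.38 and -2.39. Camera gave an adjusted p of 1.73e-05, and the adjusted p was 0.263 with an estimated correlation. In the erythroid list the 1 gene tested, Hbb-b2, did not pass (log2 fold change -1.24, SE 0.56, limma adjusted p = 0.284), and no set test was run. It passed over the list alone, but with 1 gene that is the unadjusted p and no further result. Without double-positive array 3 the value of Hbb-b2 was -0.63, and it was -1.68 without double-positive array 2.

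**Figure D3:**
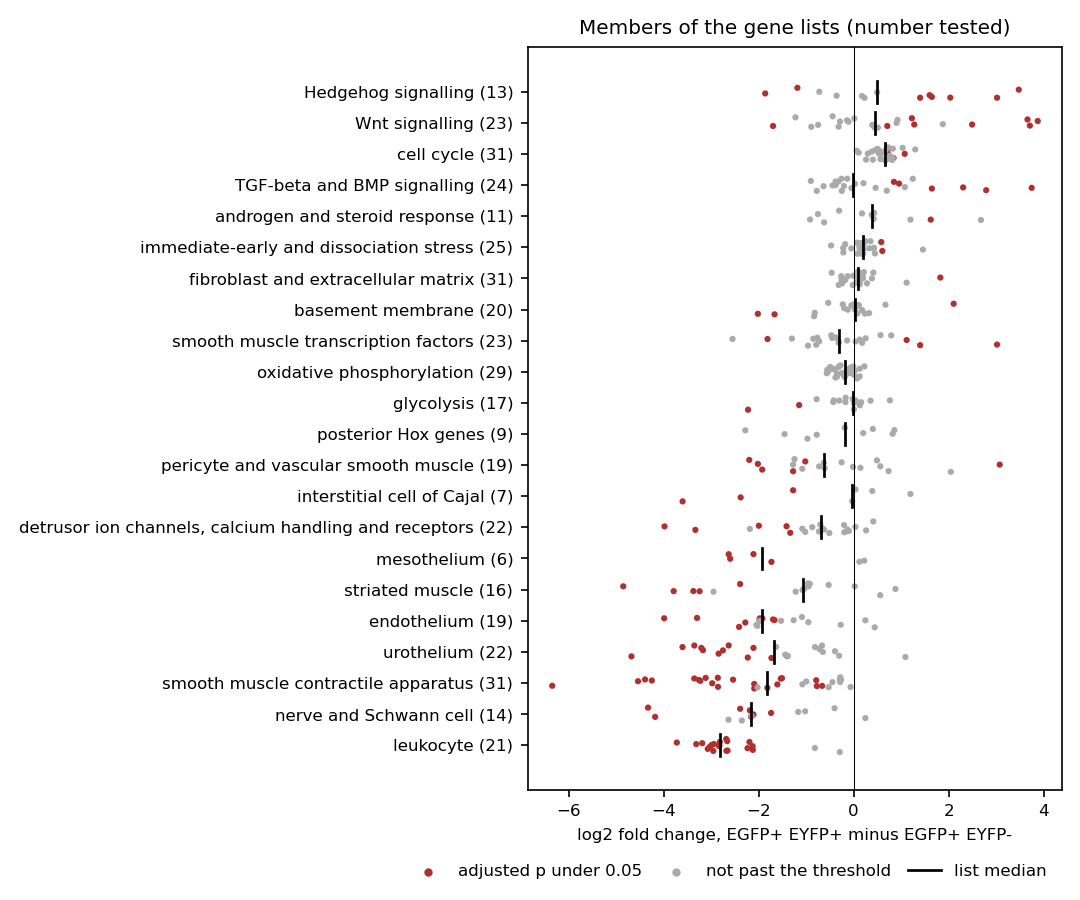
Log2 fold change (double-positive minus single-positive) of each tested member of 22 gene lists, with members past the threshold in red, others in grey and a black bar at each list's median. The leukocyte median lies at -2.82 and the contractile median at -1.82, while the fibroblast and extracellular matrix median lies at 0.10.

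In the fibroblast and extracellular matrix list, Tnc (tenascin C) rose from 4563 ± 1287 to 15824 ± 1138 (SD, n = 3; log2 fold change 1.83, SE 0.24, limma adjusted p = 0.00156). It was the 1 member of 31 that passed, also when adjusted over the list alone. Averaged over its probe sets it did not pass (1.20, adjusted p = 0.232). Col1a1 signal was 45473 ± 5789 in single-positive and 59193 ± 3853 in double-positive arrays (SD, n = 3 each), a log2 fold change of 0.39 that did not pass (limma adjusted p = 0.137). Thy1 had 1.12 and did not pass either (limma adjusted p = 0.0665), though it did without single-positive array 1 or double-positive array 3. The list was not called (camera adjusted p = 0.165, and adjusted p = 0.752 with an estimated correlation), but it was called upward without single-positive array 1 (adjusted p = 0.0187), without double-positive array 3 (0.000986) and with array weights (0.0403). In the basement membrane list of 20, Col4a6 rose (2.11, SE 0.24), Itga1 and Lama5 fell (-2.02 and -1.67), 17 did not pass, and 4 passed when adjusted over the list alone. Lama5 missed the threshold without single-positive array 2 or 3 or double-positive array 1. That list was not called (camera adjusted p = 0.770, and adjusted p = 0.841 with an estimated correlation).

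Hspa1a and Dnajb1, a heat shock protein and its cochaperone, rose by log2 fold changes of 0.58 (SE 0.13) and 0.60 (SE 0.14), and Ier2 had 0.45 and did not pass (limma adjusted p = 0.0892). These 2 of 25 immediate-early and dissociation stress genes passed, and 2 when adjusted over the list alone. The camera adjusted p was 0.0018, and the adjusted p was 0.269 with an estimated correlation. No member passed when any 1 of the 3 single-positive arrays, or double-positive array 1 or 2, was left out, and 4 passed without double-positive array 3. No gene of oxidative phosphorylation passed among 29 with limma, and 0 passed when adjusted over the list alone. Cox7a2, Uqcrfs1 and Atp5b had log2 fold changes of -0.53, -0.50 and -0.39 that did not pass. The camera call of that list was downward (adjusted p = 0.00619), its adjusted p was 0.30 with an estimated correlation, and it was lost without single-positive array 1 (0.0774) and with array weights (0.102).

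Of 17 glycolysis genes Pfkp (platelet phosphofructokinase) and Eno3 (muscle enolase) fell, with log2 fold changes of -2.22 (SE 0.25) and -1.15 (SE 0.30), and 15 did not pass, Ldhb (-0.78) among them. When adjusted over the list alone, 4 passed, 1 higher and 3 lower. Eno3 missed the threshold without any 1 of the 6 arrays, with adjusted p between 0.0527 and 0.187. The list was not called (camera adjusted p = 0.207, and adjusted p = 0.382 with an estimated correlation). In the androgen and steroid list of 11, Hsd11b1, which regenerates active glucocorticoid, rose (log2 fold change 1.62, SE 0.32), and was the 1 to pass when adjusted over the list alone. Esr1 (2.68, SE 0.87) and Cyp7b1 (-0.75, SE 0.26) did not pass, and Esr1 had 1.46 without single-positive array 1 and 3.51 without single-positive array 3. Hsd11b1 missed the threshold without single-positive array 2 or 3 or double-positive array 1 or 2. The list was not called (camera adjusted p = 0.280, and adjusted p = 0.394 with an estimated correlation). None of 9 posterior Hox genes passed with limma, and 3 passed when adjusted over the list alone. Without double-positive array 3, 2 fell, without double-positive array 2, 1 rose, and with array weights 1 rose and 2 fell. Hoxd10, Hoxd9 and Hoxa10 had log2 fold changes of -2.28 (SE 0.64), -1.45 (SE 0.41) and 0.86 (SE 0.25), with Hoxd10 at -1.41 without double-positive array 1 and -2.73 without double-positive array 3, and the list was not called (camera adjusted p = 0.736, and adjusted p = 0.752 with an estimated correlation).

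Of the 22 lists tested, 15 passed with camera, 5 of them upward and 10 downward, while 0 passed with an estimated correlation, where the lowest adjusted p was 0.0601. With fry, which tests whether the genes of a list move one way without setting them against other genes, 9 passed. RNA quality was read from control probe sets. The ratio of 3' to 5' Actb signal was 5.16 ± 2.65 in double-positive and 4.89 ± 1.45 in single-positive arrays (SD, n = 3 each; exact two-sided permutation p = 1), and that of Gapdh was 19.4 ± 3.87 and 15.9 ± 4.45 (SD, n = 3 each; exact two-sided permutation p = 0.4). Signal of an 18S rRNA probe set was 46280 ± 30703 and 34315 ± 11299 (SD, n = 3 each; exact two-sided permutation p = 0.6). Double-positive array 3 had the highest Actb and Gapdh ratios of the 6 arrays (8.02 and 23.9) and the lowest 18S signal (12655, against 53360 and 72824 in the other double-positive arrays). Its Pearson's r with the single-positive arrays was 0.913 to 0.923, against 0.890 to 0.902 for the other double-positive arrays, and 1077 genes past the threshold were counted without it. The smallest p that 3 against 3 arrays allow is 0.1.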

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

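The ratio of 3' to 5' Actb signal as a covariate was an alternative chosen after seeing the data; the others were fixed before. No gene of the 857 changed sign in any setting in which it was tested. With array weights 1345 genes passed the threshold, with 435 genes higher in double-positive arrays and 910 genes lower in double-positive arrays, and 849 of the 857 were among them. Leaving out 1 array gave 474 to 1077 genes, 160 to 349 higher and 314 to 728 lower, and fewer arrays lower the power. The other settings gave 631 (no variance trend) to 1014 genes. That highest count came from the replicate block, with 817 shared. The numbers were not taken to pair the samples: same-numbered arrays had correlations of deviations of 0.19, 0.05 and 0.02. Single-positive arrays 1 and 2 correlated best with the double-positive array of the same number, and single-positive array 3 with double-positive array 2 (0.09). Pairing was not excluded by these values. Every probe set tested on its own gave 925 of 27022. Acta2 passed with the mean of its probe sets (-2.48, adjusted p = 0.00155) and without shared probe sets (-4.31, adjusted p = 9.2e-05), since other probe sets then stand for it. Leaving out 1 array gave Acta2 values of -0.20 to 0.063, with the sign turned without double-positive array 3, and Actg2 kept its call at -2.76 to -2.31. Lists past the threshold numbered 0 with an estimated correlation, 9 with fry and 14 to 17 without 1 array. Directions turned for lists that were not called: extracellular matrix under quantile normalization (adjusted p = 0.383) and transcription factors with fry (0.883). Without 1 array 4 list results turned, among transcription factors, posterior Hox genes and basement membrane. Over all 6 such settings, turned or not, the adjusted p of these lists was 0.413 to 0.976, 0.410 to 0.842 and 0.454 to 0.899. Hoxa10 turned with the mean of its probe sets (-0.038). The cause was not tested. Of 329 values of the 28 genes of largest change in other settings, 323 kept their call, and 165 of 168 without 1 array. Many low signals lie under 100, where signal over background limits the folds.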

Other observations

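The tests for exchanged labels, for a lower share of the main cell type, for scaling and for the splits of the arrays were chosen after the results were seen, as were the families and genes of the next paragraphs. For the lower share of the main cell type the deciding test was changed more than once with results known, and its threshold was moved from 0.05 to 0.05 over 3 after the p of 0.0351 given below was seen. The tests of 3' bias, dim transcripts, second marker lists and second target genes were written before their results were seen.

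Genes were grouped by the stem of their symbol, which gave 320 stems and 640 tests of called genes against all tested genes, and 5 passed a Benjamini-Hochberg adjusted p of 0.05. Members of a family are not independent. T-box transcription factors rose in the double-positive arrays for 4 of 8 (adjusted p = 0.00159). Tbx3, which patterns mesenchyme in many organs, rose from 1969 ± 878 to 9214 ± 1774 (SD, n = 3; log2 fold change 2.29, SE 0.33, limma adjusted p = 0.00245), and Tbx20, Tbx2 and Tbx5 had log2 fold changes of 1.32, 1.49 and 2.13, the last from a mean log2 value of 5.89 in single-positive arrays, below the level of the filter. Bone morphogenetic proteins rose for 4 of 7 (adjusted p = 0.00159), the genes named in the report. Outside these families, Aldh1a2, which makes retinoic acid, rose from 1339 ± 519 to 8171 ± 1029.5 (SD, n = 3; log2 fold change 2.66, limma adjusted p = 0.00119), and Gata5, a transcription factor, had 1.99 (limma adjusted p = 0.0022). Of 20 genes tested under the stem Aldh, 3 rose (Aldh1a1, Aldh1a2 and Aldh2) and 3 fell (Aldh1a3, Aldh1a7 and Aldh3b1).

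C-type lectins fell for 7 of 13 (adjusted p = 0.000261), chemokines of the Ccl family for 6 of 13 (adjusted p = 0.00159) and colony stimulating factor receptors for 4 of 6 under the stem Csf (adjusted p = 0.00653). Clec7a, a receptor of myeloid cells for fungal glucans, had a log2 fold change of -4.20 (SE 0.37), Ccl24 had -3.49 and Ccl3 had -2.80. Clec7a and Ccl24 had mean double-positive signals of 48.1 and 62.3, below the level of the filter on dim genes, so their folds rest on the offset. As single genes, Actc1, cardiac alpha actin, fell from 44525 ± 3013 to 2900 ± 3132 (SD, n = 3; log2 fold change -4.54, SE 0.62, limma adjusted p = 0.00201), and Tnnt2, cardiac troponin T, from 29145 ± 1991 to 1668 ± 997 (log2 fold change -4.36, SE 0.47, limma adjusted p = 0.000612).

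With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 857 genes and the highest other split 0, and the real split gave 15 lists and the highest other 11. In each case 1 split, the real one, gave a result as large.

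Contractile genes were lower in the double-positive libraries. Loss of signal far from the 3' end may lower long transcripts, but with the 3' to 5' Actb ratio as a covariate the list's median was -1.817 and 20 of its genes passed; the ratio hardly differs between the groups, so the covariate moved the median little, and it corrects for that ratio alone. An exchange of the group labels could give the pattern too, and it cannot be told apart from a difference between the populations: Acta2 on the probe set used, with a signal near the top of the range, had a log2 fold change of -0.06532, and no probe set for the reporters was used here. Lower values of the other Acta2 probe sets (-4.31, limma adjusted p = 0.000954, and -3.07, limma adjusted p = 0.141) go with an exchange without deciding it. Actg2 was lower too (-2.54), but both populations were sorted as positive for its reporter, so it does not bear on an exchange. A biological difference between the populations stays open.

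Markers of other cell types were lower in the double-positive libraries. Loss of dim transcripts is argued against by the median of 76 leukocyte, Schwann, urothelium and endothelium genes, -2.138, which lay below all of 10000 random lists matched on level (-0.339 to 0.309). A lower share of the main cell type in single-positive libraries would lower that type's own genes there. The contractile list went the other way, with 21 of 31 members higher there past the threshold and none lower. Its median was -1.817 (fry adjusted p = 0.00383, and camera adjusted p = 0.0650 with an estimated correlation). That difference was known before the test was chosen, and a change within the muscle cells could hide a lower share. The list therefore cannot decide on the share. Of the 2 other tests tried for a lower share, the leukocyte and pericyte medians differed by -2.193 (permutation p = 2e-05, 100000 resamples). That pair was picked from seen medians, and pericytes may belong to the sorted cells. The medians of the 4 lists differed by up to 1.136 (permutation p = 0.0351, under 0.05 but above 0.05 over 3). Genes were not independent in either test. Cells or RNA of those 4 types in the single-positive libraries are a candidate explanation. Of 49 genes in second leukocyte, Schwann, epithelial and endothelial lists, 87.76% had a lower value, 7, 6, 3 and 7 of 16, 11, 10 and 12 past the threshold. Each list passed camera (adjusted p = 9.79e-10, 1.34e-06, 0.000802 and 6.71e-07), the epithelial list not with an estimated correlation (adjusted p = 0.0375, 0.0331, 0.0987 and 0.0356). These p-values were adjusted over the second lists alone, while 0 of the 22 first lists passed with an estimated correlation. Both sets of lists rest on the same 6 arrays, so the second is not independent support. Both populations were sorted as EGFP positive, and the purity of the sort is not known here. Clec14a, an endothelial gene, rose (1.73), and Sox10 of the first list was not lower.

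Of the Hedgehog, Wnt, and TGF-beta and BMP lists, 18 members rose in the double-positive libraries, Gas1, Cdon and Nkd2 fell, and no list passed with an estimated correlation (adjusted p = 0.0882, 0.183 and 0.111). Scaling to an equal trimmed mean would raise all other genes after a loss of muscle transcripts, as far as these lay within the trimmed range. The brightest 2% of probe sets lie outside it. The median of all tested genes was 0.02053, against 2.17 for the 18 members, picked because they rose. The medians of the whole lists were 0.49, 0.44 and -0.0072. Higher Wnt and Hedgehog activity may be a source: a second list of 9 target genes had a mean of 0.3634 with 8 of 9 higher, but did not pass (camera adjusted p = 0.0544). Apcdd1 alone rose (1.56), and Ccnd1 was lower without passing (-0.93, SE 0.25, limma adjusted p = 0.0549). The test leaves such activity open. A different mix of mesenchymal cells in the sorted populations was not tested.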
